A study of Mus musculus with 2 samples.

How the data were processed

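The data were a raw UMI count table per library, as deposited by the authors, with 32287 features: the mm10 genes plus the reporter features mGFP and CreERT2. Per the labels, the libraries were made with a SeekOne droplet 3′ kit, while another field names 10x Genomics. The aligner, the counting program and its version, and the way barcodes were called as cells are not given in the sources used here. The deposited count values were whole numbers and were used as they stood. The 2 libraries are named GFPhi and GFPlo after their labels, and other label fields call the same fractions GFP-positive and GFP-negative. Which part of the reporter the mGFP feature covers is not given in the sources used here, so it may also count unrecombined transcript. Positions came from GENCODE vM21 (mm10), which matched 32158 of 32285 Ensembl identifiers (99.6%), and 78 symbols occurred more than once.

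The questions, gene lists, markers, filters, tests and alternatives were chosen before the data were examined, except where the text says otherwise. A cell was kept with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. This left out 305 barcodes of GFPhi (2.92%) and 385 of GFPlo (3.12%), and 22084 cells remained. Median mitochondrial shares were 2.32% and 1.92% before the filter. Summed over the cells, ribosomal protein genes took 18.1% and 18.3% of UMIs, haemoglobin genes 0.00339% and 0.000205%, and cardiomyocyte genes 0.00188% and 0.00131%. Scrublet, run on each library with an expected 6% of doublets, marked 0 and 1 barcodes, under the 0.5% below which it was taken as not having worked, so no doublets were removed and keeping called doublets, meant as a further alternative, had nothing to change.

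Cells of both libraries were clustered together. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 gave 25 clusters. Libraries were not integrated, since library and group are the same. Chemokines, Cdkn2a and other genes the questions are about were left out of the variable genes, and so were the reporter features, the last by a choice made after the data were seen. A cluster was named for 1 of 19 marker classes when at least 3 of its markers were 2-fold higher there than in other cells and detected in at least 10% of its cells. A cluster whose median UMIs were more than 3-fold below those of its libraries, with no marker of that class among its 10 leading genes, got no name. This held for cluster 6, with 4 macrophage markers, and cluster 10, with 4 fibroblast markers. A class with a cluster that listed more markers of another class than of its own among its 10 leading genes failed the marker check and was compared by cluster number. This was the case for macrophages, by cluster 4, and fibroblasts, by cluster 13. After the data were seen, 2 or more own markers among the 10 leading genes were given priority in naming, since cluster 17 would otherwise have been named cardiomyocyte-like. Lymphocyte clusters were split again into 12 subclusters, named against all other cells by a choice also made after the data were seen. A cluster mostly of 1 library may hold that library and not a cell type.

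Expression was compared as the ratio of CPM in GFPhi over GFPlo, from UMIs summed over cells, with exact conditional intervals; shares of cells have exact Clopper-Pearson intervals and levels exact Poisson intervals, all at 95%. With 1 library per group these cover counting error only, and neither the spread between mice nor a test could be had. No ratio was given unless both libraries had a UMI and one had 3. A count of 0 was read as allowing up to 3 counts. Fold lower means the inverse ratio. Groups with at least 100 cells in each library were compared within themselves: endothelial-like (clusters 8 and 19), lymphatic endothelial-like (cluster 22), mesothelial-like (clusters 20, 21 and 24) cells and cluster 13.

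Genes were named by rule. Cdkn2a, Ccl8, Ccr1, Ccr2, Ccr8, Gzma, Gzmb, Prf1, Ncr1, Cd3e and Cd8a were always named, 1 further gene of this rule is not reported here, and for each comparison so were the 10 genes in each direction with the largest differences by the nearer bound of the interval, among genes with at least 50 CPM and 20 UMIs. Mitochondrial, ribosomal, haemoglobin and unnamed predicted genes were passed over. Names beyond these, such as the leading genes of clusters, list examples, Cdkn1a, Cdkn2b and Gdf15, were chosen after their values were seen. The 15 gene lists were p16 and cell cycle inhibitors, secretory factors of senescence, chemokines, chemokine receptors, cytotoxic lymphocyte, extracellular matrix, antigen presentation, interferon response, inflammatory, lipid and phagocytic, tissue-resident macrophage, cell cycle, hypoxia and glycolysis, angiogenic endothelial and dissociation stress. Members with at least 10 CPM in a library were measured, with a prior count of 0.5, and a member past 1.5-fold was counted as higher or lower. The median of a list was set against 10000 random lists of the same size, drawn within 20 bins of expression, as a description.

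Free RNA puts UMIs into cells that do not express a gene, and the share of cells with a UMI rises with depth. Shares of cells with a UMI were therefore taken after every cell was thinned to 1000 UMIs. Thinning evens depth and drops cells with fewer UMIs, but does not take off free RNA. This left 9572 cells of GFPhi and 11098 of GFPlo. Lymphocytes and endothelial-like cells served as background for Ccl8. For cells outside macrophage-like clusters, the level of 10 macrophage genes was given as a share of their level in macrophage-like cells of GFPhi.

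Simulated counts with the same depths, drawn by Poisson from the pooled profile of each comparison, checked the calculation. Poisson error is what the intervals assume, so coverage near 95% was built in. Uneven counts between cells and RNA of other cells were not simulated. In the whole libraries (24545 genes) median recovered folds were 1.50, 2.00 and 4.00 for true folds of 1.5, 2 and 4, and intervals covered the truth for 97.1%, 95.5% and 92.4% of the 68, 66 and 66 changed genes. In endothelial-like cells (18204 genes) they were 1.48, 1.99 and 3.95 (94.1%, 93.9% and 92.4%). In lymphatic endothelial-like cells (16269 genes) they were 1.49, 1.99 and 4.00 (92.6%, 97.0% and 98.5%). In mesothelial-like cells (21850 genes) they were 1.49, 2.00 and 3.98 (95.6%, 90.9% and 92.4%), and in cluster 13 (20357 genes) 1.50, 1.97 and 3.97 (92.6%, 98.5% and 93.9%). In each comparison 20 of 20 genes named by the rule were changed genes, and a list of 12 genes raised 2-fold gave a median of 1.98, 1.94, 1.98, 2.01 and 1.95. A list of 12 unchanged genes gave 0.981, 0.988, 0.975, 0.985 and 0.996, at percentiles of 3.54, 62.5, 42.4, 28.3 and 76.6. A percentile can thus lie near an end without a change.

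Alternatives were: minimum of 500 or 200 genes; mitochondrial limit of 10% or none; the 5% of cells with most UMIs left out; Leiden resolution 0.5 or 2.0; all genes allowed as variable; each library clustered alone; median-of-ratios scaling; means over cells; thinned counts; clusters of a class weighted alike; lists with no minimum or 50 CPM; and positive cells counted unthinned or by at least 2 UMIs. Those chosen after the data were seen are named with their values under the processing part of the closing section. Rules changed after the first values under the alternatives were seen were the minimum of UMIs for a ratio, no value where nothing is left after other cells' RNA is subtracted, list medians only from 3 or more measured members, and the overlap of leading genes no longer read as a main result. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and scikit-learn 1.9.0.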

Results

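The 2 droplet libraries held non-cardiomyocytes of the infarct zone of mice carrying p16-2A-CreER and the R26-mTmG reporter. In this reporter, Cre turns a cell and its descendants from membrane tomato to membrane GFP. Tamoxifen was given on day 5 after myocardial infarction, and the cells were taken on day 7 and sorted into a GFP-high and a GFP-low fraction. Each fraction gave 1 library, named GFPhi and GFPlo here, so there are no replicates and no test of a difference was possible. All intervals are exact 95% intervals and cover counting error only. The count table of GFPhi held 10430 barcodes with 91343549 unique molecular identifiers (UMIs), and that of GFPlo held 12344 barcodes with 104855204 UMIs. After the filter, 10125 cells of GFPhi and 11959 cells of GFPlo remained, with medians of 6899 and 7712 UMIs per cell. Levels are given in CPM of the UMIs summed over the cells compared.

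The reporter and p16 came first, since the sort rests on them. The mGFP transcript was higher in GFPhi, at 33.8 CPM (3074 UMIs) against 22.8 CPM (2380 UMIs) in GFPlo, a ratio of 1.48 (1.41–1.57). Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471–89294653 of mm10, minus strand), whose locus encodes the cell cycle inhibitor p16 and the p53 activator p19Arf, was lower in GFPhi. It had 214 UMIs (2.35 CPM, 2.05–2.69) in GFPhi and 493 UMIs (4.71 CPM, 4.31–5.15) in GFPlo, and was 2.00-fold lower (1.70–2.36). Cdkn1a, the p53-induced inhibitor p21, was 3.91-fold higher in GFPhi (3.84–3.98), and Cdkn2b, the p15 inhibitor beside Cdkn2a, was 2.75-fold lower. The CreERT2 transcript had 1 UMI in GFPhi and 5 UMIs in GFPlo. Without the macrophage-like cells described next, the Cdkn2a ratio was 1.03, the Cdkn2b ratio 1.10 and the mGFP ratio 1.94. Transcript of the unrecombined reporter may be part of the mGFP counts, counts from the 3′ end cannot tell p16 from p19Arf, and GFP marks the activity of the p16 promoter around tamoxifen, not at harvest.

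The next comparison asked which cells each fraction held. Macrophage-like cells filled most of GFPhi and were rare in GFPlo, while fibroblast-like cells were the largest group of GFPlo. Clusters 1, 2, 3, 4, 5 and 9, all carrying macrophage markers, together made up 74.9% of GFPhi (74.0–75.7) and 0.753% of GFPlo (0.606–0.924), which is 7582 against 90 cells. Clusters 11, 12 and 13, carrying fibroblast markers, together made up 3.34% of GFPhi (338 cells) and 51.1% of GFPlo (50.2–52.0), a share 15.3-fold lower in GFPhi (13.7–17.1). These sums are given as arithmetic only, because cluster 4 also showed the monocyte marker Ccr2 and cluster 13 the mural marker Acta2, so neither class passed the marker check. With each library clustered alone, where names rest on that library, macrophage-like cells were 33.9% of GFPhi and 1.48% of GFPlo, and fibroblast-like cells 3.91% and 19.6%. With those clusters instead given the joint-clustering class of most of their cells, the macrophage-like share of GFPhi stayed within 74.0–75.7%.

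Other cell types were also scarcer in GFPhi. Mesothelial-like cells made up 5.38% of GFPhi (4.95–5.84) and 17.8% of GFPlo (17.1–18.5). Endothelial-like cells made up 2.83% (2.52–3.18) and 9.69% (9.17–10.2), and lymphatic endothelial-like cells 1.03% (0.840–1.24) and 2.42% (2.16–2.72). Mural-like cells made up 0.217% of GFPhi and 1.35% of GFPlo, and neutrophil-like cells 0.0296% and 0.803%. Shares within a library are tied to each other, so the shares outside the macrophage clusters were also taken, a choice made after the shares were seen. That base of 2543 and 11869 cells still held 1011 and 200 cells of cluster 6. Cluster 6 passed 4 macrophage markers but got no name, having few UMIs and no macrophage marker among its 10 leading genes. The base was therefore also taken without cluster 6. Fibroblast-like cells remained 3.87-fold scarcer in GFPhi (3.47–4.33) with cluster 6 and 2.37-fold (2.13–2.66) without it. Mesothelial-like cells turned to a higher share in GFPhi, 21.4% against 17.9% with cluster 6 and 35.6% against 18.2% without it. So did endothelial-like cells, 11.3% against 9.76% and 18.7% against 9.93%, and lymphatic endothelial-like cells, 4.09% against 2.44% and 6.79% against 2.49%. Neutrophil-like cells remained scarcer, 6.86-fold (2.28–33.8) with cluster 6 and 4.20-fold (1.40–20.7) without it, while mural-like cells were at 1.58-fold (1.01–2.59) and 0.967-fold (0.617–1.59), the last not separable. Clusters 0, 6 and 10, which got no name, together held 10.9% of GFPhi (10.3–11.6) and 8.87% of GFPlo (8.37–9.40).

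**Figure D1:**
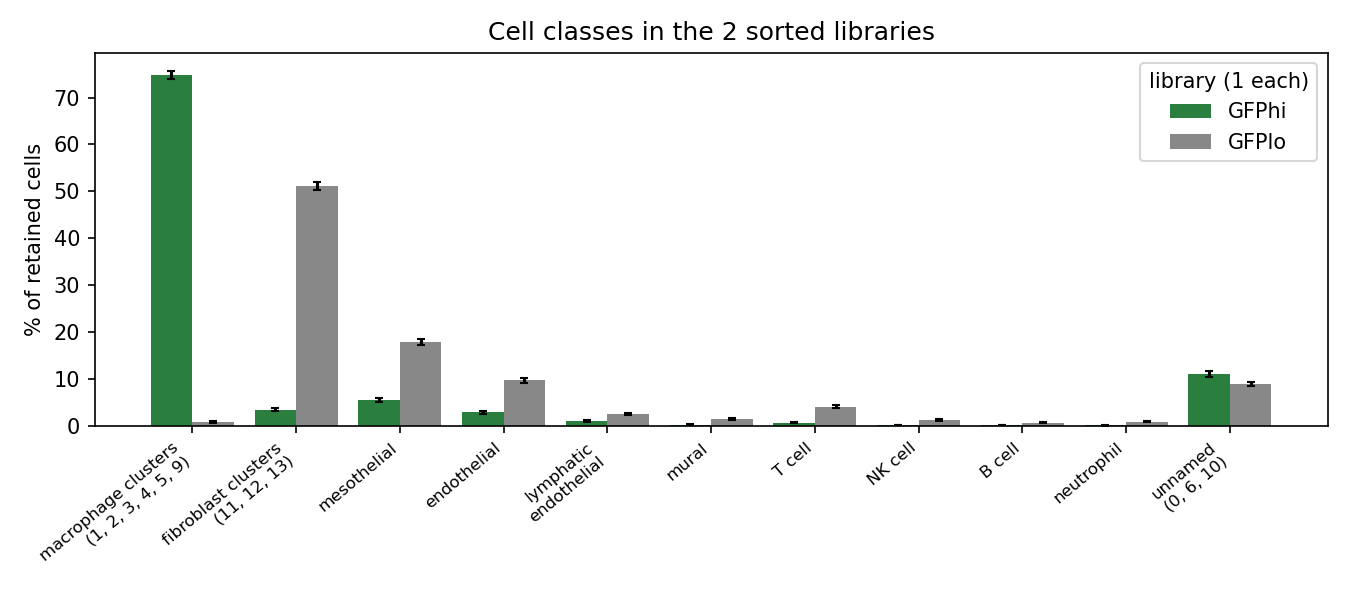
Bars give the share of retained cells (%) in each cell class or named sum of clusters for the GFPhi and GFPlo libraries (1 each), and error bars give exact 95% intervals of counting error. The macrophage-like clusters stand at 74.9% in GFPhi and 0.753% in GFPlo, and the fibroblast-like clusters at 3.34% and 51.1%.

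Within these sums the clusters differed in their leading genes. Among macrophage-like cells of GFPhi, cluster 4 was the largest with 23.9% of the library and led with the MHC class II genes H2-Eb1, H2-Aa and Cd74, beside Ccr2. Cluster 9 held 17.7% of GFPhi and 1 cell of GFPlo, and led with Gdf15, Apoe and Ms4a7. Cluster 2, with 15.7%, led with Mmp12, Gpnmb, Lgals3 and Spp1, genes of lipid-laden and phagocytic macrophages. Cluster 3, with 11.5%, led with Cd163, F13a1, Cbr2, Timd4 and Folr2, genes of tissue-resident macrophages. Cluster 5, with 3.96%, led with the cycling genes Birc5 and Mki67, and cluster 1 (2.03%) held cells with few UMIs. Among fibroblast-like cells of GFPlo, cluster 11 (20.9%) led with Pi16 and Scara5, cluster 12 (12.6%) with the matrix genes Comp, Thbs4, Fmod and Cilp, and cluster 13 (17.6%) with Ptn, Sfrp1, Cthrc1 and Acta2. In GFPhi these 3 clusters held 0.622%, 0.928% and 1.79%.

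Summed over each whole library, the largest differences in GFPhi were macrophage genes. Fcrls was 824-fold higher (533–1349), the monocyte chemokine Ccl12 549-fold (415–742), Ms4a7 452-fold and the complement genes C1qc, C1qb and C1qa 364-, 325- and 319-fold. C3ar1, Npy, Mmp12 and Cbr2 were 229-, 235-, 198- and 224-fold higher. Genes lower in GFPhi were those of neutrophils and fibroblasts. The neutrophil markers S100a9 and S100a8 were 168-fold (130–220) and 14.8-fold lower, and Pi16, Svep1, Pcolce2, Crispld2, Islr and Ebf2 were 12.6-, 11.5-, 11.4-, 11.3-, 10.9- and 10.9-fold lower. Abca8a and Cytl1 stood at 0.0587 and 0.0624 of their GFPlo level. Several of these genes are markers that define the classes, so they repeat the difference in cell shares. In CPM the median ratio of all genes was −0.32 log2 in the whole libraries and −0.10 log2 in mesothelial-like cells, which median-of-ratios scaling takes off.

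The fixed gene lists moved with the cell classes, and each median ratio is given with its percentile among random lists of like expression. Macrophage lists were higher in GFPhi. The tissue-resident macrophage list had a median ratio of 44.5 (percentile 100) with 7 of 9 measured members at least 1.5-fold higher, among them Cd163 at 495-fold. All 10 antigen presentation genes were higher, with a median of 8.32 (100), including Cd74 at 13.1-fold, the invariant chain of MHC class II. The lipid and phagocytic list had a median of 8.07 (100) with 10 of 14 higher, among them Gpnmb at 142-fold. The inflammatory list had a median of 3.10 (100) with 8 of 12 higher, among them Cd14 at 56.4-fold and Il1rn at 54.3-fold. Chemokines had a median of 2.84 (100) with 13 of 21 higher and 5 lower, and all 5 measured chemokine receptors were higher with a median of 18.9 (99.99).

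Matrix and lymphocyte lists went the other way. All 20 extracellular matrix genes were lower in GFPhi with a median ratio of 0.178 (percentile 0), among them the cartilage-type matrix gene Comp at 0.111 and the matricellular gene Postn at 0.125 of their GFPlo level. The cytotoxic lymphocyte list had 3 measured members with a median of 0.0707 (0), and Gzma and Nkg7 were 20.3- and 14.2-fold lower. The angiogenic endothelial list had a median of 0.418 (3.62) with 4 of 5 lower, a direction not kept without the macrophage-like cells (0.0523 log2). The secretory factors of senescence went both ways: 12 of 23 were higher, led by Mmp12 and Ccl8, and 9 were lower, among them Igfbp7 at 5.27-fold, for a median of 2.05 (100), which turned to −0.371 log2 among members with at least 50 CPM. In the list of p16 and cell cycle inhibitors, 3 of 8 measured members were higher, Gdf15 at 62.7-fold and Cdkn1a among them. Another 4 were lower, and the median was 0.798 (30.6). Cdkn2a was not among the 8, since its 2.35 CPM in GFPhi and 4.71 CPM in GFPlo lay below the minimum for measured members. Medians were 1.06 (89.9) for interferon response, 1.00 (88.0) for cell cycle, 1.30 (98.8) for hypoxia and glycolysis with Arg1 15.7-fold higher, and 1.40 (98.2) for dissociation stress with Atf3 3.54-fold higher.

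The series title names Ccl8, a chemokine that attracts monocytes and lymphocytes, and the question was which cells held its transcript. In the summed libraries Ccl8 (ENSMUSG00000009185, chromosome 11, 82115185–82116799 of mm10, plus strand) was 74.9-fold higher in GFPhi (67.4–83.4), with 23069 against 354 UMIs. Macrophage-like clusters held 97.4% of the Ccl8 UMIs of GFPhi, and cluster 3 alone, the one led by tissue-resident genes, held 57.6%. Its level there was 1553 CPM (1527–1580), 9.19-fold that of the other macrophage-like clusters summed (8.95–9.44). Cluster 9 stood at 259 CPM (250–267), cluster 1 at 228 (178–286), cluster 4 at 171 (165–178), cluster 5 at 162 (152–173) and cluster 2 at 96.7 (92.2–101). Chemokines were left out of the genes that formed the clusters.

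The 90 macrophage-like cells of GFPlo held 6 Ccl8 UMIs, all in the 54 cells of cluster 4, at 21.9 CPM (8.03–47.6) against 171 CPM in cluster 4 of GFPhi. The other macrophage-like clusters had too few cells in GFPlo to compare. Of the 354 UMIs of GFPlo, 61.6% lay in fibroblast-like clusters, 18.9% in mesothelial-like cells and 16.7% in cluster 0. The 59 UMIs of cluster 0 came from only 4 of its 675 cells. With every cell thinned to 1000 UMIs, 9.89% of GFPhi cells (9.30–10.5) and 0.216% of GFPlo cells (0.139–0.322) had a Ccl8 UMI, against 22.9% and 1.22% unthinned. In cluster 3 of GFPhi the thinned share was 33.6% (30.8–36.4) and the unthinned share 52.6% at a median of 6363 UMIs. As background, lymphocytes of GFPhi showed 0% thinned (0 of 108 cells, interval up to 3.36%) and 3.45% unthinned at a median of 1856.5 UMIs, and endothelial-like cells of GFPhi showed 0.810% thinned and 5.23% unthinned at a median of 4651 UMIs. Ccl8 was also higher in the GFPhi cells of other types, by 7.92-fold in cluster 13 (6.09–10.3) and 6.31-fold in mesothelial-like cells (4.77–8.44). It was at 30.5 against 0.523 CPM in lymphatic endothelial-like cells (34 and 1 UMIs) and 11.2 against 0.218 CPM in endothelial-like cells (22 and 1 UMIs). In all 4 groups other macrophage genes were higher too, as described below.

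Other chemokines divided the macrophage-like clusters of GFPhi between them. Cluster 3 also led in Cxcl13, a B cell attractant, 100-fold over the other clusters (66.8–157), and in Ccl24, an eosinophil attractant, 19.4-fold (16.8–22.3). Ccl6, Ccl7, Ccl12 and Ccl9 were 6.12-, 4.23-, 3.34- and 3.12-fold higher there, with Ccl6 at 1358 CPM. Ccl2, a monocyte attractant, was high in clusters 5 and 3, at 1301 and 1230 CPM, and Ccl7 was also 2.04-fold higher in the cycling cluster 5. Cluster 4, the MHC class II cluster, led in chemokines that attract T and NK cells: Ccl5 was 7.74-fold, Cxcl9 4.65-fold and Cxcl10 2.85-fold over the other clusters, and Ccl3 and Ccl4 were 2.11- and 2.06-fold. In cluster 3, Ccl4 was at 0.443 and Cxcl10 at 0.414 of the other clusters.

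**Figure D2:**
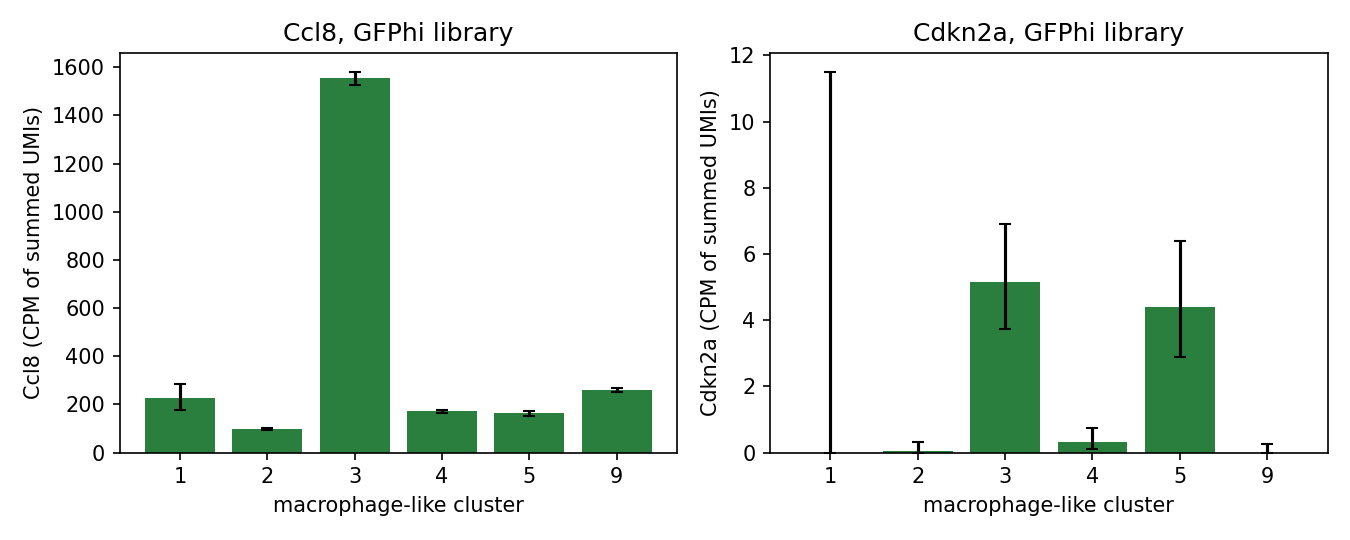
Bars give the level (CPM of summed UMIs) of Ccl8, left, and Cdkn2a, right, in the 6 macrophage-like clusters of GFPhi, and error bars give exact 95% intervals of counting error. Ccl8 stands at 1553 CPM in cluster 3, while Cdkn2a is seen in clusters 3 and 5 at 5.14 and 4.39 CPM.

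Cdkn2a was seen in mesothelial-like, lymphatic endothelial-like and fibroblast-like cells and in part of the macrophage-like clusters. Within GFPhi the macrophage-like clusters held 36.0% of its UMIs at a joint level of 1.22 CPM, and these lay in cluster 3 at 5.14 CPM (3.74–6.90, 44 UMIs) and cluster 5 at 4.39 CPM (2.90–6.39, 27 UMIs). Cluster 4 stood at 0.314 CPM and cluster 2 at 0.0564 CPM, and no Cdkn2a UMI was seen in the 1792 cells of cluster 9, which allows up to 0.212 CPM. Higher levels were seen in the cycling mesothelial-like cluster 21, with 14.6 CPM in GFPhi (9.47–21.6) and 10.6 in GFPlo (8.29–13.3), and in lymphatic endothelial-like cells, with 11.7 (6.21–19.9) and 9.41. Fibroblast-like cluster 13 had 10.2 CPM in GFPhi (7.36–13.8) and 5.84 in GFPlo (4.92–6.88). Endothelial-like cells stood at 1.02 and 1.96 CPM. In GFPlo, fibroblast-like clusters held 46.9% and mesothelial-like cells 40.4% of the Cdkn2a UMIs.

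The title also names cytotoxic lymphocytes, and lymphocytes made up a smaller share of GFPhi. Lymphocyte clusters made up 1.15% of GFPhi (0.948–1.37, 116 cells) and 6.46% of GFPlo (6.03–6.92, 773 cells). NK cells were 16.8-fold scarcer in GFPhi (7.95–42.6, 7 against 139 cells) and B cells 4.73-fold. The NK cells pool subcluster 5, with 3 against 91 cells, and subcluster 9, with 4 against 48. Subcluster 9 also had the T cell marker Trac among its leading genes. In GFPlo it held 55 Cd8a UMIs, against 0 in subcluster 5. T cells as a whole were 6.95-fold scarcer (5.28–9.29; 58 against 476 cells), a pool of unlike subclusters. Subcluster 0, with the effector genes Nkg7, Ifng and Cxcr6, was 13.9-fold scarcer (7.36–29.5; 10 against 164 cells). Subcluster 2, which held most T cells of GFPhi and carried the thymocyte gene Dntt, had 43 against 68 cells, a share 1.34-fold lower (0.901–2.01). Subclusters 10 and 7, which also carried Dntt, were 30.2-fold (10.1–149, 3 against 107 cells) and 48.3-fold (8.32–1939, 1 against 57 cells) scarcer. Subcluster 1, without a name, had 30 against 22 cells, a ratio of 1.61 (0.899–2.93). Single subclusters were not set against the cells outside the macrophage-like clusters. Outside the macrophage-like clusters the NK cell share was 4.25-fold lower in GFPhi (2.01–10.8), and 2.61-fold (1.23–6.60) without cluster 6 as well. The T cell share was 1.76-fold lower (1.34–2.35) and that of all lymphocyte clusters 1.43-fold (1.17–1.75), but neither was separable without cluster 6, at 1.08-fold (0.819–1.44) and 0.875-fold (0.719–1.07). B cells were separable on neither base, at 1.20-fold (0.642–2.43) and 0.733-fold (0.393–1.49).

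Genes of cytotoxic killing were also lower. Gzmb, a granzyme, was 29.4-fold lower in GFPhi (13.3–81.2; 6 against 203 UMIs), Prf1, which encodes perforin, 12.3-fold (6.03–29.2) and the NK receptor gene Ncr1 17.3-fold (8.17–43.8). Gzma was 20.3-fold lower (15.9–26.2), Cd3e of the T cell receptor complex 5.58-fold (4.79–6.53) and Cd8a 4.79-fold (3.78–6.13). Without the macrophage-like cells these stood at 0.0911 (Gzmb), 0.229 (Prf1), 0.186 (Ncr1), 0.145 (Gzma), 0.550 (Cd3e) and 0.664 (Cd8a) of their GFPlo level. The NK-like subcluster 5 of the lymphocytes held 849 Gzma, 49 Gzmb and 63 Prf1 UMIs in its 91 cells of GFPlo, and 3 cells of GFPhi.

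The chemokine receptor genes Ccr1, Ccr2 and Ccr8 were looked up in every class. Ccr1 was 19.0-fold (15.6–23.4) and Ccr2 7.55-fold (6.95–8.21) higher in GFPhi as a whole. Ccr8, with 3 UMIs in GFPhi and 8 in GFPlo, gave a ratio of 0.431 (0.0736–1.80). Summed over the macrophage-like clusters, Ccr2 was at 64.2 CPM in GFPhi (62.2–66.2) and 302 CPM in GFPlo (255–355), and Ccr1 at 26.3 CPM (25.1–27.6) and 51.0 CPM (33.0–75.3). These sums hold different clusters, since cluster 4, which has Ccr2 among its leading genes, held 54 of the 90 cells of GFPlo and 2423 of the 7582 of GFPhi. Cluster 4 held 274343 of 490412 UMIs of these cells in GFPlo and 15933477 of 62864212 in GFPhi. Its larger share alone is therefore too small to give the whole Ccr2 difference. In GFPlo, Ccr2 was at 254 CPM in NK cells (215–298), 315 CPM in lymphocytes without a name (228–424) and 35.6 CPM in T cells, and neutrophil-like cells of GFPlo had 244 CPM of Ccr1 (183–320). The T cell value pools unlike subclusters. Among their GFPlo cells, the effector subcluster 0 held 52 Ccr2 UMIs among 446495 UMIs, while the Dntt-carrying subclusters 7 and 10 held 0.

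Expression within a cell type was compared in the 3 classes and 1 cluster with at least 100 cells in each library. In endothelial-like, lymphatic endothelial-like and mesothelial-like cells and in cluster 13, the 10 genes that led as higher in GFPhi were all at least 10-fold higher in macrophage-like cells, such as C1qa, C1qb, Ms4a7, Lyz2 and Ctss. The median of 10 macrophage genes stood at 6.96%, 10.3%, 2.88% and 6.20% of its macrophage level in these 4 groups. In both endothelial groups the genes that led as lower were fibroblast genes, such as Col1a1, 15.3-fold and 18.5-fold lower. The leading genes named below therefore come from a further choice, made after these values were seen. It left out every gene with a higher level in macrophage-like cells of GFPhi than in the compared group of either library.

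Endothelial-like cells of GFPhi showed higher cycling genes. Of 12 measured cell cycle genes 11 were at least 1.5-fold higher, with a median ratio of 2.33 (percentile 100). Ube2c and Prc1 of mitosis were 4.42- and 4.51-fold higher. Gpihbp1, the capillary anchor of lipoprotein lipase and a leading gene of cluster 19, was 3.88-fold higher, Rbp7 5.19-fold and the neuropeptide gene Gal 14.2-fold (9.84–21.1). The angiogenic endothelial list had a median of 1.48 with 5 of 10 higher, among them the VEGF receptor gene Kdr at 2.58-fold and the tip cell gene Esm1 at 3.18-fold. Cluster 19, led by Gpihbp1, Prnd and Aplnr, held 32.1% of the endothelial-like cells of GFPhi and 14.8% of those of GFPlo. By UMIs, which the ratios sum, it held 1101020 of 1961303 in GFPhi and 1043373 of 4596622 in GFPlo. The remaining cells lay in cluster 8, led by Igf2, Sost, Nrg1 and Npr3. This difference in mix may account for part or all of the higher Gpihbp1, and ratios of these genes within each cluster are not given here. With both clusters weighted alike, the median log2 ratio of the cell cycle list was 0.65 and that of the angiogenic list 0.06.

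Lymphatic endothelial-like cells of GFPhi held more reporter and less of the cycling genes. Their mGFP was 5.66-fold higher (4.34–7.44, 219 against 38.7 CPM), but 6 of the 104 cells of GFPhi held 68.9% of its UMIs. Without the 5% of cells with most mGFP in each library it was 2.61-fold (1.80–3.84). That choice was made after the values were seen and selects on the value compared. Of 12 cell cycle genes 10 were lower, with a median ratio of 0.489 and Mki67 at 0.299. Ednrb, an endothelin receptor gene, was 3.19-fold higher, the semaphorin genes Sema3f and Sema3a 2.16- and 1.95-fold, and Ccl21a, which draws dendritic cells into lymphatics, 1.86-fold. Chemokine, receptor, antigen presentation and lipid lists were higher here (medians of 9.83, 28.5, 6.75 and 1.82), beside the 10.3% macrophage share, and all 20 matrix genes were lower. With RNA of other cells taken off, the chemokine list was at 2.03 log2, antigen presentation at 0.31 and lipid and phagocytic at 0.12 log2, and receptors gave no value. Fibroblast RNA stood at 11.4% of its fibroblast level in these cells of GFPlo and at 10.5% in endothelial-like cells of GFPlo, and Lum in the former and Col1a1 in the latter turned to 1.09 and 1.11 once it was taken off.

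Mesothelial-like cells of GFPhi had 3.82-fold more Cdkn1a (3.68–3.97; 492 against 129 CPM) and 1.93-fold more mGFP (1.70–2.19). Cdkn2a was lower, at 0.684 (0.511–0.907), and 1.10 with the clusters weighted alike. Cluster 24, led by Slurp1, Krt14 and Msln, held 56.7% of these cells in GFPhi, and cluster 20, led by Pnoc, Enpp2 and Wnt4, 64.6% in GFPlo. Beside the macrophage genes, Cst9 was 4.71-fold and Slurp1, a leading gene of cluster 24, 4.44-fold higher in GFPhi. Aspn, Col8a1 and Postn, genes of the matrix, were 5.66-, 5.24- and 3.57-fold lower. Aspn, Mfap4 and Cthrc1 led as lower here and in both endothelial groups, where fibroblast RNA was seen in GFPlo. Fibroblast RNA was not taken off in mesothelial-like cells, so its part in the lower matrix genes was not tested. Of 20 matrix genes 12 were lower (median 0.626), as were 9 of 12 cell cycle genes (0.600). With the clusters weighted alike neither median stayed past 1.5-fold, at −0.42 log2 for matrix and 0.0246 log2 for cell cycle.

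Cluster 13, the fibroblast-like cells led by Ptn and Sfrp1, had 3.34-fold more Cdkn1a in GFPhi (3.16–3.53; 477 against 143 CPM). Cdkn2a was 1.75-fold higher (1.21–2.48), while mGFP was at 1.03 (0.818–1.28). Ly6c1 was 3.73-fold higher (3.40–4.09), the hyaluronan receptor gene Cd44 2.86-fold, the lubricin gene Prg4 2.63-fold and Serpina3n 2.19-fold. Genes that led as lower were Pdlim3, 2.39-fold, Angptl7, 2.26-fold, Wfdc18, 2.20-fold, and Lrrc17, 2.18-fold, then Gas1, Fbln1, Mfap2, Ptn, Eln and Sfrp2 from 1.99- to 1.78-fold. The matrix list as a whole had a median of 0.824 with 0 of 20 past the 1.5-fold size. The list of p16 and cell cycle inhibitors had a median of 1.38 (percentile 100), and chemokines one of 1.71, beside the 6.20% macrophage share. With that RNA taken off, 0 lists stayed past 1.5 in cluster 13. Which of the 10 genes led as lower depended on the filter: 2 of 10 remained without the 5% of cells with most UMIs, and Wfdc18 turned to 1.75-fold higher with a mitochondrial limit of 10%.

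**Figure D3:**
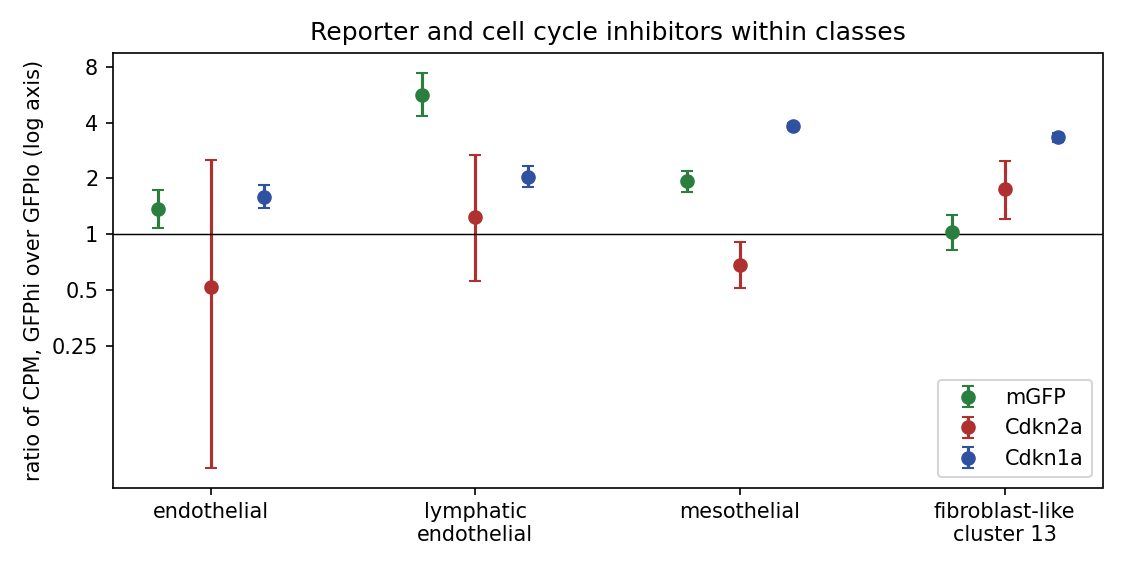
Points give the ratio of GFPhi over GFPlo (logarithmic axis) for mGFP, Cdkn2a and Cdkn1a in the 4 groups with at least 100 cells per library, and error bars give exact 95% intervals of counting error. Cdkn1a lies above 1 in all 4 groups, while the interval of mGFP includes 1 in cluster 13 (0.818–1.28). In endothelial-like cluster 8 alone, which is not drawn, the Cdkn1a ratio was 0.854 (0.669–1.08).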

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

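The tests in this part were written down before their results were seen, except leaving out the cells with most mGFP, while the patterns themselves were seen first. No biological explanation was tested, since the design gives no group beyond the sort.

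Macrophage-like cells made up 74.9% of GFPhi and 0.753% of GFPlo (33.9% and 1.48% with each library clustered alone). With those clusters matched to classes by shared cells, the share of GFPhi stayed within 74.0–75.7%. A loss of macrophages from GFPlo by the filter is argued against, since their share there reached at most 0.919% under the filter settings. Swapped labels are argued against as well, since the mGFP ratio of GFPhi over GFPlo lay above 1 by its lower bound in 3 of 4 cell groups. Whether the reporter transcript separates the gates stays open. The lower bound of the mGFP ratio was above 2 in 1 of the 4 groups, lymphatic endothelial-like cells, and the upper bound was below 2 in another 2. Without the 5% of cells with most mGFP, the lower bound was 2.12 in mesothelial-like and 1.80 in lymphatic endothelial-like cells. This choice selects on the value compared. In mesothelial-like cells it took 29.8% of the mGFP UMIs of GFPhi and 45.3% of those of GFPlo, so it cannot decide the question. Macrophage-like cells themselves had 29.2 CPM of mGFP in GFPhi and 22.4 CPM (11 UMIs) in GFPlo, against 22.8 CPM in GFPlo as a whole. Marking of macrophages by p16, uptake of GFP and autofluorescence of macrophages in the sort may each contribute, and none was tested.

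Macrophage genes, Ccl8 among them, were higher in the other cell types of GFPhi than in those of GFPlo. Free macrophage RNA in the droplets fits these values, since Ccl8 stood within a factor of 3 of the median share of 10 macrophage genes in each group, with ratios of 0.442, 0.815, 1.07 and 1.31, although single genes ranged from 0.148% to 7.79% in endothelial-like cells. Doublets of a macrophage and another cell cannot be told apart from it, because the 5% of cells with most macrophage UMIs held between 37.4% and 61.4% of those UMIs. In GFPhi, Ccl8 lay in 15 of 287 endothelial-like (22 UMIs), 79 of 545 mesothelial-like (208 UMIs) and 47 of 338 fibroblast-like cells (169 UMIs). Free RNA, doublets or both may account for much of the Ccl8 in these cells, and their own expression of it was not separable.

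Among macrophage-like clusters, Ccl8 was highest in cluster 3, and Cdkn2a was high there and in cluster 5, whose intervals overlapped (3.74–6.90 and 2.90–6.39 CPM). RNA of mesothelial-like or fibroblast-like cells is argued against, since 4 abundant genes of these cells stood at a median of 0.552% of their level, against 98.1% for Cdkn2a. Depth is argued against by a narrow margin for the other clusters pooled: after thinning, 0.434% of cluster 3 cells (0.141–1.01, 5 cells) had a Cdkn2a UMI against 0.0478% (0.00985–0.139, 3 cells). Cluster 5 alone held 2 of those 3 cells and stood at 0.501% (0.0608–1.80), so which of clusters 3 and 5 was higher stays open. A candidate explanation is that some tissue-resident macrophages carry both transcripts, and whether single cells hold both was not tested.

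Some results went opposite ways in different cell types, and the difference between cell types was not tested. The cell cycle list had a median ratio of 2.33 in endothelial-like cells (0.65 log2 with the clusters weighted alike), 0.489 in lymphatic endothelial-like cells and 0.600 in mesothelial-like cells, the last 0.0246 log2 with the clusters weighted alike. Cdkn2a had a ratio of 1.75 in cluster 13 and 0.684 in mesothelial-like cells, the last 1.10 with the clusters weighted alike.

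Signals were also seen in cells and barcodes that no comparison used. The 305 barcodes of GFPhi left out by the filter held 55 Ccl8 UMIs (158 CPM), against 0 in the 385 of GFPlo. The mGFP transcript was at 44.0 CPM in the GFPhi cells of cluster 0 (14.4 in GFPlo), 127 CPM in cluster 6 (64.3 in GFPlo) and 107 CPM in cluster 10 (40.5 in GFPlo), clusters that got no name. These clusters had few UMIs, with medians of 813, 1214 and 2220. Their median mitochondrial shares were 0.513%, 10.6% and 7.12%, against 2.29% in retained cells of GFPhi and 1.91% in those of GFPlo.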

How the results depend on the processing

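Alternatives chosen after the data were seen were leaving out the 6% of cells with the highest doublet score, matching classes by shared cells, and leaving out macrophage-like cells. So were taking off RNA of other cells and leaving out the 5% of cells with most macrophage UMIs. Of the main results, 216 values were kept, 69 moved and 1 reversed, and of the others, 2661 were kept, 609 moved and 11 reversed. Kept means a share or ratio within its main interval, a count within 1.5-fold, or a list median on the same side of 1.5-fold. No paired analysis was possible because each group had 1 library. In every alternative that changed the cells or clusters, macrophage-like cells held most or, clustered alone, 33.9% of GFPhi, and from 0.744% to 1.48% of GFPlo; all lymphocyte clusters ranged from 1.08% to 1.23% and from 6.25% to 6.66%. Ccl8 in the whole libraries ranged from 6.40 to 123 and mGFP from 1.45 to 1.94. Where a value moved, the cause was not tested.

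With at least 500 genes, macrophage-like cells were 78.0% of GFPhi, fibroblast-like cells 4.44% and 63.9%, lists at 1/1.5 or less in mesothelial-like cells 1, and Ccl8 in cluster 3 over the other clusters 8.86. With 200 genes fibroblast-like cells were 2.21% and 45.1%. With a mitochondrial limit of 10%, macrophage-like cells were 79.7%, fibroblast-like cells of GFPlo 54.2%, low lists in endothelial-like cells 2, Ccl8 in cluster 3 8.74 and Wfdc18 in cluster 13 1.75 (reversed). With no limit, the shares were 73.2% and 52.0%. Without the 5% of cells with most UMIs, macrophage-like cells were 77.7%, fibroblast-like cells 2.97% and 59.7%, the Ccl8 ratio 107, and Cd8a in mesothelial-like cells 1.04 and Cdkn2b in cluster 13 0.964 (both reversed). Without the 6% highest doublet scores, fibroblast-like cells were 2.90% and 52.5%, and lists past 1.5 were 4 higher and 2 lower in endothelial-like and 2 higher in lymphatic endothelial-like cells.

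Leiden 0.5 gave 73.2% macrophage-like cells in GFPhi and 49.5% fibroblast-like cells in GFPlo. Leiden 2.0 gave 2.21% and 45.0% fibroblast-like cells, and all variable genes 2.24% and 45.4%. With each library clustered alone, macrophage-like cells were 33.9% and 1.48%, fibroblast-like cells 3.91% and 19.6%, higher lists in endothelial-like cells 4, and Ccl8 in cluster 3 6.88. Matched by shared cells, these were 1.48% macrophage-like cells in GFPlo and 3.91% and 49.2% fibroblast-like cells. The macrophage-like share of GFPhi then stayed within its interval of 74.0–75.7%.

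Median-of-ratios scaling gave ratios of 0.624 for Cdkn2a, 93.6 for Ccl8 and 1.86 for mGFP, and 1 low list in mesothelial-like cells. Means over cells gave 123 for Ccl8, 1.74 for mGFP, 2 low lists in endothelial-like cells and 8.46 for Ccl8 in cluster 3. Thinned counts gave 113 for Ccl8, 1.70 for mGFP, 1.01 for Cd3e in endothelial-like cells (reversed), 1 low list in lymphatic endothelial-like cells and 5 high lists in cluster 13. With clusters weighted alike, mesothelial-like cells had Cdkn2a at 1.10 and cell cycle at 0.0246 log2 (both reversed) and 0 low lists. Lists with no minimum gave 5 high and 2 low in endothelial-like, 7 high in lymphatic endothelial-like, 1 high and 4 low in mesothelial-like cells and 5 high in cluster 13. Lists with 50 CPM gave 1 low list and secretory factors of −0.37 log2 (reversed) in the whole libraries and 5 high lists in endothelial-like cells. Of thinned cells, 4.82% and 0.0360% had at least 2 Ccl8 UMIs, and of unthinned cells 22.9% and 1.22% had at least 1.

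With RNA of other cells taken off, Col1a1 in endothelial-like cells was 1.11 and Lum in lymphatic endothelial-like cells 1.09 (both reversed). Low lists were then 2 in endothelial-like and 4 in mesothelial-like cells, and high lists 2 in lymphatic endothelial-like cells and 0 in cluster 13. In mesothelial-like cells and cluster 13 only macrophage RNA was taken off, and fibroblast RNA was left in. Of the named genes, 14 of 36 in endothelial-like cells, 4 in lymphatic endothelial-like cells, 5 in mesothelial-like cells and 10 in cluster 13 had nothing left and gave no value. Without the cells with most macrophage UMIs, endothelial-like cells had 2 low lists. Without macrophage-like cells, the whole-library ratios were 1.03 for Cdkn2a and 1.10 for Cdkn2b (both reversed), 6.40 for Ccl8 and 1.94 for mGFP, and the angiogenic list was at 0.0523 log2 (reversed). Called doublets kept was not run, since none had been removed.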

Other observations

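The list of p53 targets in this part was fixed after Cdkn1a had been seen, and so were the choices of thymocyte genes, of single clusters and of leaving out the cells with most mGFP. Cdkn1a was higher in the GFPhi cells of all 4 groups, at 1.60 (1.39–1.83) in endothelial-like, 2.05 (1.79–2.34) in lymphatic endothelial-like and 3.82 (3.68–3.97) in mesothelial-like cells and 3.34 (3.16–3.53) in cluster 13. In endothelial-like cluster 8 alone its ratio was 0.854 (0.669–1.08). Macrophage-like cells had 668 CPM of Cdkn1a in GFPhi. The excess in GFPhi was 54.4% of that level in mesothelial-like cells, 50.1% in cluster 13, 32.8% in lymphatic endothelial-like and 10.1% in endothelial-like cells, where 10 macrophage genes stood at medians of 2.88%, 6.20%, 10.3% and 6.96%. In cluster 13, 8 of 14 measured other p53 targets were at least 1.5-fold higher, with a median ratio of 1.58 (percentile 100), among them Eda2r at 3.92, Ccng1 at 1.93 and Mdm2, the p53 inhibitor, at 1.83. Mesothelial-like cells had 4 of 13 higher and a median of 1.24 (99.98). Endothelial-like cells had a median of 0.967 (30.2), lymphatic endothelial-like cells 1.17 (97.9) and the whole libraries 1.08 (93.9). After thinning, the median of cluster 13 was 1.22 (percentile 88.0) and that of mesothelial-like cells 1.53 (100). Cluster 24 alone had a median of 1.48 and cluster 20 alone 1.13, with Cdkn1a at 3.64 and 2.35.

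The lymphocyte groups held further types. Subcluster 6, with 43 cells of GFPlo and 3 of GFPhi, held 27 Il17a UMIs and 77 Cxcr6 UMIs in GFPlo, genes of innate-like T cells. Dntt, the terminal transferase gene of thymocytes and early lymphoid cells, had 427 UMIs in the 107 GFPlo cells of subcluster 10 and 240 in the 57 of subcluster 7, and Ptcra had 48 in subcluster 10. Subcluster 2 held 60 Dntt UMIs in 43 cells of GFPhi and 75 in 68 cells of GFPlo. Rag2 had 14 UMIs in subcluster 10 of GFPlo, and Rag1 had 0 in all lymphocyte subclusters. NK-like subclusters 5 and 9 held 110 and 41 Ccr2 UMIs in GFPlo.

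Depth also differed between the libraries within cell types. All cells outside the macrophage-like clusters had medians of 3409 UMIs in GFPhi and 7734 in GFPlo, and T cells 1601.5 and 3512. Mesothelial-like cells had medians of 28308 UMIs in GFPhi and 13973 in GFPlo, cluster 13 had 20025 and 10312, and lymphatic endothelial-like cells 7978 and 4705.5. In lymphatic endothelial-like cells of GFPhi, a single cell held up to 38 of the 244 mGFP UMIs. Without the 5% of cells with most mGFP, the mGFP ratio was 2.61 (1.80–3.84) in lymphatic endothelial-like, 1.63 (1.20–2.21) in endothelial-like and 2.50 (2.12–2.94) in mesothelial-like cells, and 1.17 (0.883–1.53) in cluster 13. The cells left out were picked by the value compared and held unequal parts of the mGFP UMIs of the libraries, so these ratios are a description only.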
